A study of Homo sapiens with 42 samples.

How the data were processed

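N6-methyladenosine (m6A), a methyl mark on adenosines inside messenger RNA, was profiled by m6A-seq in HepG2, a human hepatocellular carcinoma cell line. In m6A-seq, fragmented mRNA is pulled down with an antibody against m6A and sequenced beside the unselected RNA, called input. Per the labels' protocols, cells carried lentiviral short hairpin RNAs (shRNAs) under puromycin selection, mRNA was fragmented by sonication, and stranded libraries were made from input and from immunoprecipitated (IP) RNA. The 42 samples form 14 groups of 3 libraries, an input and an IP group for each of 7 conditions: a control shRNA, METTL3, METTL14, WTAP and SETD2 #1, and SETD2 #2 with a control shRNA of its own. The labels number the replicates 1 to 3 and do not say whether they came from separate cultures. A set means here the conditions that share a control, the first set being that of METTL3, METTL14, WTAP and SETD2 #1. Whether the sets were made at different times is not given.

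The submitters' processing notes name FastQC 0.11.5, TopHat2 2.1.1 and the genome build hg19. Per the labels, the authors called peaks with exomePeak on replicates 1 to 3 together, which gave 1 list per condition. The exomePeak version and the gene annotation are not given in the sources used here. Each deposited table gives a p-value of IP against input per peak in a column headed score, its log10 and the log10 of the false discovery rate (FDR), which are scores without a fixed range, and a fold enrichment, a linear ratio of IP over input. Per the file headers, each peak also has a strand, a gene identifier and 1 or more blocks, which leave out the introns. The largest FDR in the tables was 0.05. A shorter deposited list per condition held exactly those peaks of the table with a p-value of at most 1e-05 and a fold enrichment of at least 2. Fold enrichment and p-value are the authors' values and were used to describe, rank or filter peaks within a list. Median fold enrichment was also compared between lists. The number of reads per library is unknown from the files used, so the precision that depth gives each peak is unknown too.

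Repeated rows with the same strand and blocks were counted once, which removed 11 to 21 rows per list. Peaks were compared by overlap with bedtools 2.31.1, and a peak was called absent from another list when no peak on the same strand shared at least 1 base of its blocks. Further values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and not the spread between cultures. With 1 list per condition there is no p-value between conditions. Absence from a list means that no peak was called there, which depends on read depth, transcript level and enrichment as well as on methylation.

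Coincidence of losses was the number of control peaks absent from both of 2 lists. It was set against the product n1 × n2 / N, where n1 and n2 are the peaks absent from each list and N the peaks counted, and against 10000 shuffles of the losses within 5 equal classes of the control list by fold enrichment. Classes by p-value, chosen before the data were examined, were used as well. The shuffles moved single peaks and ignored that peaks of a gene can be lost together, so their ranges may be too narrow. Mantel-Haenszel odds ratios over the same classes have 95% intervals from 300 resamples of genes, or 500 where the controls were separate, and 200 for the ratio of odds ratios within the first set and for the alternatives of the comparison of positions within genes. The comparison of the 5'-most with the 3'-most peak of a gene, the comparison of chromosomes, classes by fold enrichment and p-value together, 10 classes by p-value, classes with peak width, the restriction to peaks whose gene had another, non-overlapping peak in both compared lists, the METTL3, METTL14 and WTAP lists in the place of SETD2 #1, ranking by p-value in the account of peak strength, widths of matched peaks, peaks absent from all 5 knockdown lists, and the ratio of odds ratios among METTL3, METTL14 and WTAP to those with SETD2 #1 were added after the data were examined. A restriction to genes with any peak in both SETD2 lists was discarded, because it selects peaks by whether they were lost.

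The methods were tested on simulated data made from the 33672 peaks of the control list. Of 25.0% of peaks removed, 23.7% were called absent, because removed peaks can overlap other peaks of their list, and the call differed from the removal for 1.25% of peaks. Unrelated losses were drawn at a fixed rate within each p-value class. They gave an odds ratio of 0.99 within p-value classes and 3.01 within fold enrichment classes, so the latter leave a chance excess. The value near 1 was set by this design. Whether loss that varies with p-value inside a class leaves an excess was therefore not tested. When 1418 peaks were added to both losses, observed minus expected was 901, since the expected number rises with the losses. A doubled odds of loss at the 5'-most peak, planted on the same class rates, was recovered as 2.04. The simulated odds ratios and the check with added peaks used the removals themselves and not the overlap calls.

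The rule for named items, set before the data were examined, took the genes of the 8 control peaks absent from each knockdown list and of the 3 knockdown peaks absent from the control list with the highest fold enrichment, among peaks with a p-value at or better than the median of their list, and 10 for the METTL3, METTL14 and WTAP lists together and for both SETD2 lists together. The rule left out identifiers with no gene symbol. The files pair no symbols with their 17005 distinct Ensembl identifiers. In the gene table of assembly GRCh38.p14 used for names, the column for Ensembl identifiers was empty, so 0 could be matched there. Peaks are therefore named by position (hg19, counted from 1). Fixed gene lists, transcript regions, sequence motifs and the peaks of the targeted genes were not analysed here. The tables give no values per replicate, so replicates were neither compared nor left out in turn.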

Results

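The m6A-seq data covered HepG2 cells with reduced METTL3, METTL14 or WTAP, with reduced SETD2 through either of 2 shRNAs, and with control shRNAs. METTL3 is the catalytic subunit of the m6A methyltransferase complex, METTL14 its RNA-binding partner and WTAP an adaptor of the complex, while SETD2 is a methyltransferase of histone H3. Each condition had 3 input and 3 IP libraries, and the authors' peak caller joined them into a single list, so no value has a replicate error. Differences between lists are set against the difference between the 2 control lists. Each knockdown shares a set with its own control, while the 2 controls belong to different sets, so the difference between them includes any difference between sets and is no like-for-like value of no change. The number of reads behind each list is unknown.

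The control list held 33672 peaks in 14570 genes. The METTL3 list held 30352 peaks in 13321 genes, the METTL14 list 28841 in 12503, the WTAP list 29392 in 12947 and the SETD2 #1 list 28645 in 12862. The control made for SETD2 #2, called the second control here, held 31249 peaks in 13526 genes, and the SETD2 #2 list 29259 in 12963. Each knockdown list was thus shorter than its control, by 9.86% for METTL3, 14.3% for METTL14, 12.7% for WTAP, 14.9% for SETD2 #1 and 6.37% for SETD2 #2, while the second control was 7.2% shorter than the control. Peak blocks covered 12.2 Mb in the control list, 10.5 Mb for METTL3, 9.64 Mb for METTL14, 9.85 Mb for WTAP and 9.46 Mb for SETD2 #1, against 9.28 Mb in the second control and 8.54 Mb for SETD2 #2. The median fold enrichment given by the authors was 6.79 in the control list, 7.02 for METTL3, 6.71 for METTL14, 6.99 for WTAP and 5.32 for SETD2 #1, and 4.33 in the second control and 3.81 for SETD2 #2. Of the control peaks, 15404 (45.7%) overlapped a peak in all the other 6 lists.

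The first question was which control peaks went missing when a subunit of the methyltransferase complex was reduced. Of the control peaks, 22.8% (95% interval 22.3 to 23.2%) were absent from the METTL3 list, 29.8% (29.3 to 30.3%) from the METTL14 list and 28.8% (28.3 to 29.3%) from the WTAP list. In the other direction, 10.6% of METTL3 peaks, 12.7% of METTL14 peaks and 13.5% of WTAP peaks were absent from the control list. With overlap of at least 50% of both peaks, the absent shares were 35.1, 45.2 and 43.8% and the gains 27.9, 35.9 and 35.6%, so the share of gains depended much on the overlap asked for. The absent shares were larger than the gained shares in all 3 lists under both. Genes with a control peak and no peak at all in the knockdown list made up 12.9% for METTL3, 18.0% for METTL14 and 16.6% for WTAP. Between 65.4% and 69.7% of the absent peaks lay in genes that had another peak in the knockdown list. The controls differed from each other by a similar amount: 28.6% (28.1 to 29.0%) of control peaks were absent from the second control and 15.6% (15.2 to 16.0%) of second control peaks from the control. The METTL14 share lay above the larger of these 2 here, with whole spans (29.6% against 28.3%) and with an FDR of at most 1e-05 (29.8% against 28.3%). It did not with overlap of at least 50% of both peaks (45.2% for each) or among peaks at or above the median fold enrichment (19.1% against 22.2%). Nor did it with fold enrichment of at least 3 (30.6% against 36.8%) or in the shorter lists (29.3% against 29.6%). Genes left without a peak made up 13.4% and 6.73% between the controls.

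The control peaks with the highest fold enrichment among those absent from the METTL3 list lay on chromosome 2 from 177052965 to 177053596 on the minus strand, with 70.3-fold enrichment in the control, and on chromosome 6 from 151561164 to 151561777 on the plus strand, with 58.3-fold. The 8 peaks named by the rule ranged from 43.7-fold to 70.3-fold. From the METTL14 list, the leading absent peaks lay on chromosome 15 from 56034715 to 56035288 (minus strand, 119-fold), on chromosome 20 from 37555015 to 37555551 (plus strand, 103-fold) and on chromosome 14 from 64009523 to 64010062 (minus strand, 98.4-fold). The last of these was the only control peak of its gene, and the METTL14 list had none there. From the WTAP list, the 8 named peaks ranged from 27.0-fold to 47.1-fold. A peak of 180 bases on chromosome 11 from 110300847 to 110301026 (plus strand, ENSG00000137714.2) and a peak of 358 bases on chromosome 3 from 126668211 to 126668568 (plus strand, ENSG00000159685.10), both with 47.1-fold enrichment and a log10 p of -13.4, led the peaks absent from all 3 lists. Among gains, the highest fold enrichment in the WTAP list was 556-fold on chromosome 2 from 23608327 to 23785062 (plus strand, 4 blocks), in the METTL14 list 234-fold on chromosome 14 from 105411167 to 105413566 (minus strand), and in the METTL3 list 68.5-fold on chromosome 16 from 2891190 to 2891429 (minus strand).

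The next question was the same for SETD2. From the SETD2 #1 list, 27.0% (26.5 to 27.5%) of control peaks were absent, and 8.07% (7.76 to 8.39%) of its own peaks were absent from the control. From the SETD2 #2 list, 20.5% (20 to 20.9%) of second control peaks were absent, and 14.5% (14.1 to 14.9%) of its peaks were absent from that control. Counted over the same control peaks, the SETD2 #1 share lay below the 28.6% absent from the second control. Counted over second control peaks, the SETD2 #2 share lay above the 15.6% absent from the control. With overlap of at least 50% of both peaks, the shares (38.9% and 31.9%) lay below both control values (45.2% and 40.8%). With that overlap the gained shares were 28.1% for SETD2 #1 and 27.2% for SETD2 #2. Genes left without a peak made up 15.1% (14.5 to 15.7%) for SETD2 #1 and 10.5% for SETD2 #2. The leading absent peaks were on chromosome 19 from 51602115 to 51607543 (minus strand, 2 blocks, 146-fold) and on chromosome 7 from 98741454 to 98741693 (minus strand, 92.6-fold) for SETD2 #1. For SETD2 #2 they were on chromosome 16 from 11836406 to 11836615 (minus strand, 60.3-fold) and on chromosome 7 from 101891774 to 101892044 (plus strand, 58-fold).

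Weakly supported peaks made up most losses. In the class of control peaks with the worst p-values, 63.4% were absent from the METTL3 list, 67.0% from METTL14, 65.3% from WTAP and 70.6% from SETD2 #1, and 56.6% of such second control peaks were absent from SETD2 #2. In the class with the best p-values these shares were 0.0743%, 0.401%, 0.594%, 0.238% and 0.128%. Ranked by fold enrichment, as planned, the decline was uneven: from the weakest to the strongest class the share absent from the METTL14 list went from 54.1% to 8.58%, with 29.3% in the class before the strongest, and for SETD2 #2 it was 25.6% in the weakest and 24.9% in the strongest class. Among the 16891 control peaks with a p-value at or better than the median, 7.90% (7.50 to 8.32%) were absent from METTL14 and 7.41% (7.02 to 7.81%) from WTAP, against 2.42% (2.19 to 2.66%) from METTL3 and 3.24% (2.98 to 3.52%) from SETD2 #1. The second control lacked 7.28% (6.89 to 7.68%) of the same peaks. The absent peaks were narrow, with a median of 149 to 151 bases, against 270 to 330 bases for those present in the knockdown lists.

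**Figure D1:**
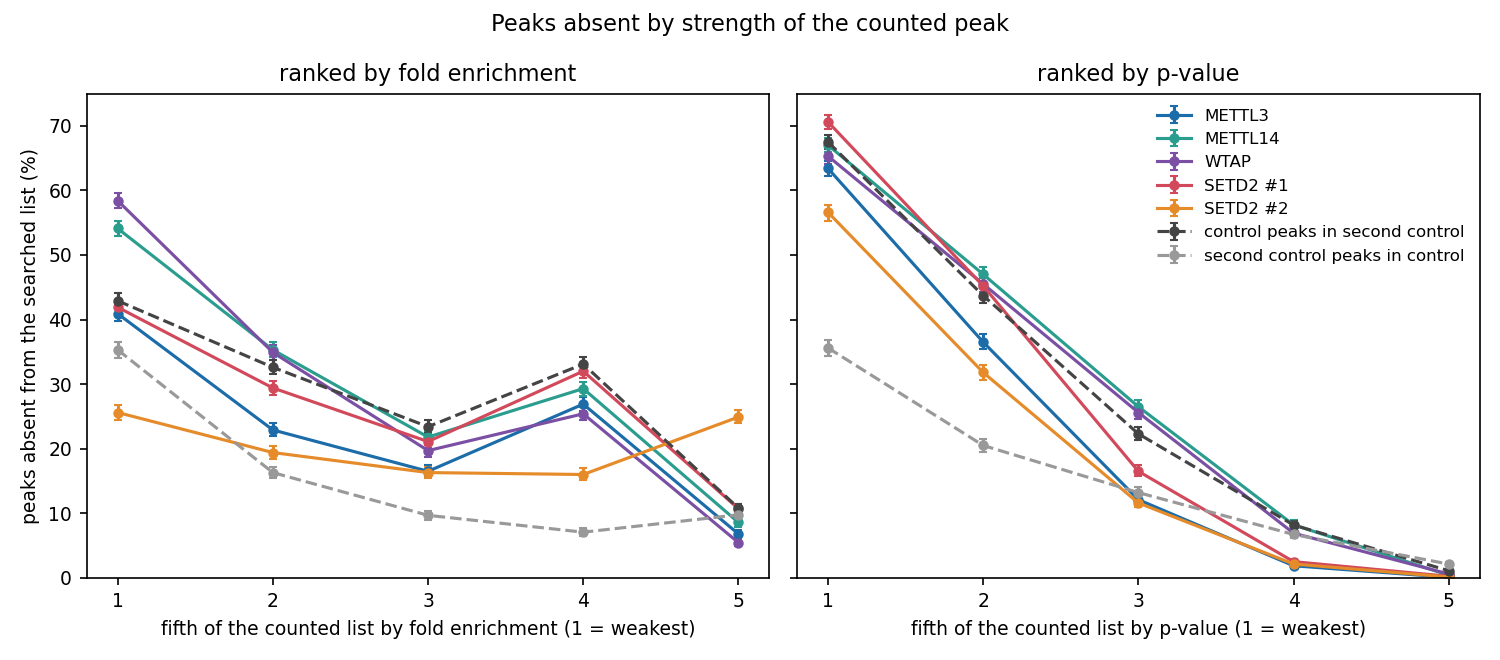
Share of peaks absent from the searched list (%, vertical axis) in 5 equal classes of the counted list, from weakest to strongest, by fold enrichment (left) and by p-value (right). Solid lines are knockdown lists against their own control, dashed lines the control lists against each other, and bars exact 95% intervals. By p-value the share absent from METTL3 fell from 63.4% to 0.0743% across the classes.

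Peaks matched 1 to 1 were more often narrower than wider in the first set of knockdowns. They were narrower for 56.7% of matched peaks in METTL3, 62.4% in METTL14, 62.2% in WTAP and 64.9% in SETD2 #1, and wider for 23.5%, 21.9%, 21.7% and 16.8%. For SETD2 #2 the shares were 44.1% narrower and 33.4% wider. The second control against the control gave 60.7% and 25.1%. The median width over whole lists was 269 bases in the control and 239 to 241 bases in the other 6 lists.

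The losses of the knockdowns that share the control coincided. METTL14 and WTAP both lacked 7684 control peaks, where n1 × n2 / N gives 2891 and shuffles within fold enrichment classes gave 3782 (95% range 3713 to 3851). METTL3 and METTL14 both lacked 6121 (product 2290, shuffled 2848, range 2780 to 2914), and METTL3 and WTAP 5920 (2209, 2851, 2786 to 2915). SETD2 #1 lacked 5604 peaks together with METTL3 (2073, 2469, 2402 to 2534), 6178 with METTL14 (2713, 3229, 3159 to 3298) and 5943 with WTAP (2617, 3205, 3138 to 3273). Within p-value classes the shuffled numbers rose to 4882 for METTL14 and WTAP, 4246 for METTL3 and METTL14, 4125 for METTL3 and WTAP, and 4265, 4926 and 4784 for SETD2 #1 with METTL3, METTL14 and WTAP, all still below the observed counts. The odds ratio within p-value classes was 15.0 (14.0 to 16.1) for METTL14 and WTAP, 8.39 for METTL3 and METTL14 and 7.40 for METTL3 and WTAP. For SETD2 #1 it was 4.79 (4.49 to 5.12) with METTL3, 3.70 with METTL14 and 3.34 with WTAP.

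Part of this coincidence may come from the shared control, whose replicates are pooled and could not be split. With the second control as an unchanged list searched with the same peaks, the odds ratio within p-value classes was 1.43 for METTL3, 1.26 for METTL14, 1.17 for WTAP and 2.32 for SETD2 #1. The second control and SETD2 #2, searched with the control peaks, gave 10.2 (9.51 to 11.0). Any difference between the sets removes control peaks from both of these lists. The value shows that lists without a common knockdown can coincide this strongly when both differ from the counted control. Whether the METTL3, METTL14 and WTAP lists differ together from the control for a reason other than the knockdown cannot be told. Within the first set, METTL3, METTL14 and WTAP coincided more with each other than with SETD2 #1: the lowest odds ratio among them was 1.54 times (1.40 to 1.71) the highest with SETD2 #1. Among peaks at or above the median fold enrichment this ratio was 1.04 (0.88 to 1.23).

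**Figure D2:**
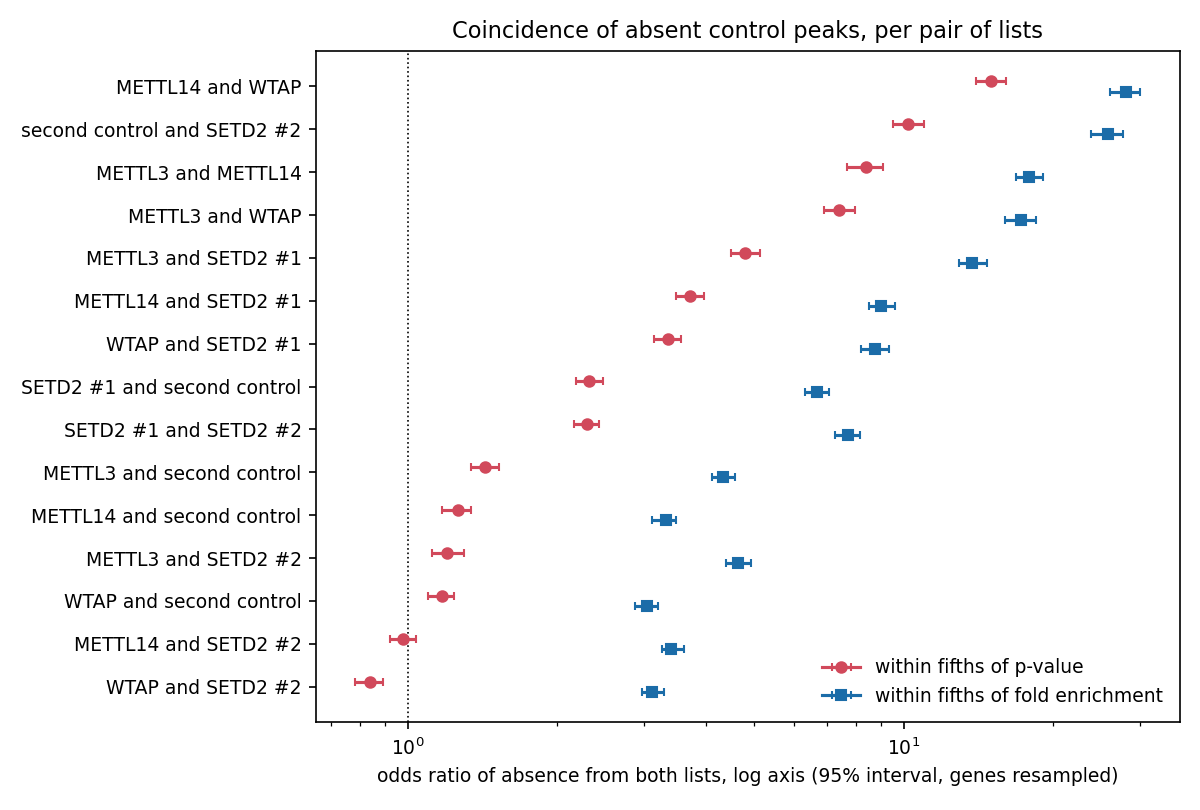
Odds ratio (log axis) of absence from both of 2 lists over the 33672 control peaks, within 5 classes of p-value (circles) or of fold enrichment (squares), for 15 pairs of lists, with 95% intervals from resampled genes. Within p-value classes METTL14 and WTAP lay highest at 15.0, followed by the second control and SETD2 #2 at 10.2.

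Whether both SETD2 shRNAs affect the same peaks was asked with separate controls, over the 24058 control peaks that overlap a second control peak. For each of them, absence from SETD2 #2 was judged for the second control peak that shared the most bases with it. A second control peak could thus count for several control peaks. By this rule both SETD2 lists lacked 1450 of the 24058 peaks. The product gave 536 and shuffles within fold enrichment classes of both controls 573 (535 to 610). Within p-value classes the expected number was 1269 (1232 to 1306), and the odds ratio was 1.59 (1.45 to 1.77). In the place of SETD2 #1, the odds ratio with SETD2 #2 was 1.05 (0.955 to 1.16) for METTL3, 0.871 (0.795 to 0.962) for METTL14 and 0.699 (0.635 to 0.765) for WTAP. With classes by both measures it was 1.69 (1.52 to 1.88) for SETD2 #1, 1.19 (1.05 to 1.35) for METTL3, 1.08 (0.969 to 1.19) for METTL14 and 0.958 (0.854 to 1.06) for WTAP. Within p-value classes, the ratio of the SETD2 #1 odds ratio to these was 1.52 (1.35 to 1.72), 1.83 (1.62 to 2.05) and 2.28 (2.01 to 2.55). Within fold enrichment classes the odds ratios were 6.23 for SETD2 #1, 4.38 for METTL3, 3.34 for METTL14 and 3.21 for WTAP, and the ratios 1.42, 1.86 and 1.94.

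Of the peaks absent from both SETD2 lists, 78 had a p-value at or better than the control median. The peak on chromosome 7 from 98741454 to 98741693 (92.6-fold) led them, followed by chromosome 2 from 120980481 to 120980836 on the minus strand (53.1-fold). The best supported of the 10 named lay on chromosome 22 from 21996550 to 21997452 (plus strand, 2 blocks, 36.7-fold, log10 p of -85.3). Of the 2312 peaks gained in SETD2 #1, 666 overlapped a second control peak, 616 a peak of the SETD2 #2 list and 158 (6.83%) a peak gained in SETD2 #2. The overlap of gains was not set against chance. The leading gains common to both lay on chromosome 1 from 24446588 to 24446916 (minus strand, ENSG00000142677.3, 6.67-fold in the SETD2 #1 list) and on chromosome 14 from 74454799 to 74462944 (minus strand, 2 blocks, ENSG00000187097.12, 3.76-fold).

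As transcript regions were not analysed here, the 5'-most peak of each gene with several peaks was compared with its 3'-most peak. From the SETD2 #2 list, 1764 genes lacked the 5'-most but not the 3'-most peak, and 764 the reverse. Peaks between these were not considered and may be absent too. For SETD2 #1 the numbers were 1800 and 1163, for METTL3 1531 and 1147, for METTL14 1570 and 1598, and for WTAP 1435 and 1693. Between the controls they were 1420 and 1478 for control peaks, and 834 and 1077 for second control peaks. Within fold enrichment classes the odds of loss were higher for the 5'-most peak in every comparison, with odds ratios of 1.84, 1.51 and 1.43 for METTL3, METTL14 and WTAP, 1.97 and 2.41 for SETD2 #1 and #2, and 1.23 and 1.22 between the controls. The measures of strength differed in direction: the 5'-most control peaks had weaker p-values than the 3'-most, with a median log10 p of -9.48 against -17.1, but a higher median fold enrichment, 10.3 against 5.38. In the second control the medians were -9.64 against -13.6 and 6.44 against 3.56. Within p-value classes the odds ratio was 2.19 (1.98 to 2.40) for SETD2 #2 and 1.01 (0.939 to 1.09) for SETD2 #1. It turned below 1 for METTL3 (0.850), METTL14 (0.594), WTAP (0.491) and between the controls (0.584 and 0.637). With classes by both measures it was 1.92 (1.74 to 2.14) for SETD2 #2, 1.10 (1.00 to 1.20) for SETD2 #1, 1.03 for METTL3, 0.849 for METTL14, 0.790 for WTAP, and 0.628 and 0.966 between the controls. The interval lay above 1 under all 3 kinds of classes for SETD2 #2 only.

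**Figure D3:**
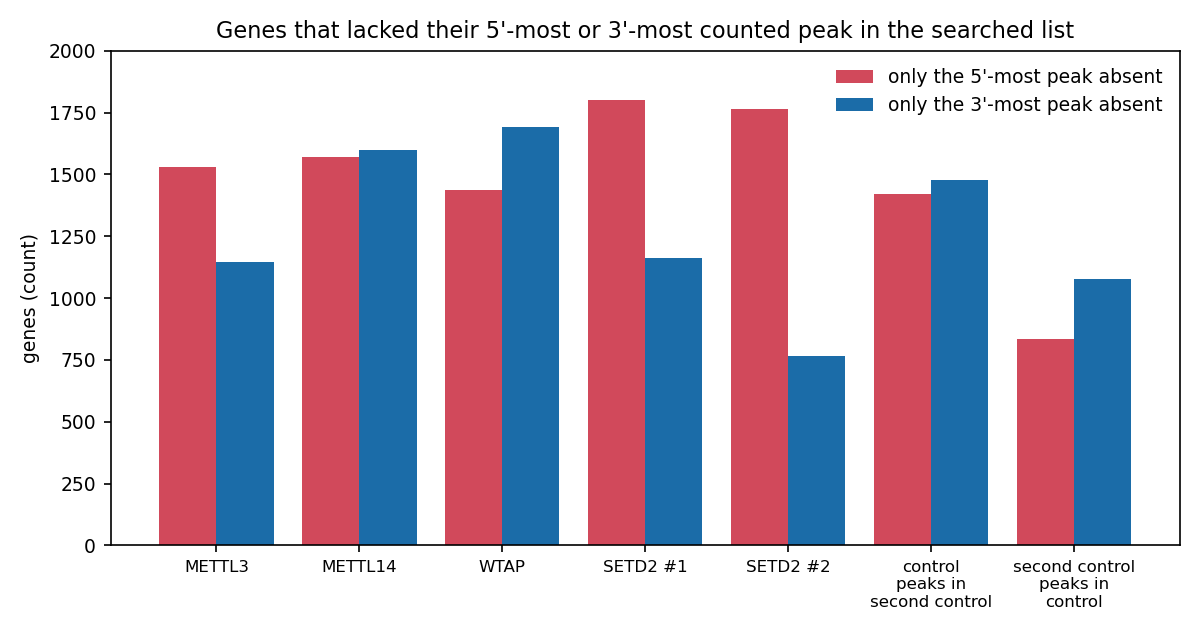
Number of genes (vertical axis) that lacked their 5'-most but not their 3'-most peak in the searched list, or the reverse, among genes with several counted peaks, for the 5 knockdown lists and the 2 control lists against each other. Peaks between these were not considered. For SETD2 #2 the numbers were 1764 and 764.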

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

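The SETD2 #2 list held 2 peaks on the mitochondrial chromosome, where its control and the other 5 lists held 0. They were counted among the peaks of that list and were not analysed separately. They lay from 577 to 647, with 1.38-fold enrichment and a log10 p of -2.49, and from 1941 to 2060, with 1.26-fold enrichment and a log10 p of -956. Both fold enrichments were below the minimum of 2 of the shorter lists.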

How the results depend on the processing

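No paired analysis was possible because the peak lists pool replicates 1 to 3, and no replicate could be left out for the same reason. Alternatives for transcript regions, gene lists and motifs were not run. Classes by fold enrichment and p-value together, the ratio of odds ratios within the first set and all settings of the 5' against 3' comparison were chosen after the data were examined. Depth is unknown and limits the calling of weak peaks. For values that changed from setting to setting, the cause was not tested. The alternatives of overlap, spans, limits and shorter lists shuffled within fold enrichment classes, where unrelated losses already gave an odds ratio of 3.01, so an excess there was expected by chance. Run again within p-value classes, added after the data were examined, all 6 of these alternatives left coincidence above the shuffled range, at 1.18 to 1.73 times the expected number for the 6 pairs sharing a control and 1.11 to 1.23 times for the SETD2 shRNAs. These ranges ignore that peaks of a gene can be lost together, and these numbers have no interval from resampled genes. Whole spans left every share of absent peaks within its counting interval, and the 8 named control peaks of each knockdown stayed absent with whole spans. Overlap of at least 50% is no test for the named peaks, as it cannot make an absent peak present. In all settings, shares below are in the order METTL3, METTL14, WTAP, SETD2 #1, SETD2 #2, then control peaks absent from the second control and the reverse, unless named.

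With overlap of at least 50% of both peaks, absent control peaks were 35.1, 45.2, 43.8, 38.9 and 31.9%, gained peaks 27.9, 35.9, 35.6, 28.1 and 27.2%, and the controls 45.2 and 40.8%. Counting only peaks at or above the median fold enrichment, absent peaks were 16.8, 19.1, 15.9, 21.4 and 19.6%, gained peaks 8.33, 10.9, 14.3, 6.54 and 10.6%, and the controls 22.2 and 8.46%. With fold enrichment of at least 3 in both lists, absent peaks were 24.3, 30.6, 30.0, 31.8 and 29.1%, gained peaks 13.7, 15.6, 16.3, 9.82 and 19.1%, and the controls 36.8 and 14.7%. With an FDR of at most 1e-05, absent peaks were 20.4, 29.8, 27.0, 25.3 and 21.4%, gained peaks 10.2, 12.6, 13.1, 6.17 and 9.86%, and the controls 28.3 and 14.4%. In the shorter lists, absent peaks were 20.4, 29.3, 27.1, 26.2 and 22.2%, gained peaks 6.82% (SETD2 #1) and 11.7% (SETD2 #2), and the controls 29.6 and 13.9%.

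The lowest odds ratio among METTL3, METTL14 and WTAP over the highest with SETD2 #1 had an interval above 1 under 7 of 8 alternatives (1.25 to 1.56), and one that held 1 among peaks at or above the median fold enrichment (1.04). The number of peaks changed by more than 1.5 times in the second control with the FDR limit (20700) and in the shorter list (20678), and in SETD2 #2 with fold enrichment of at least 3 (18883), the FDR limit (18004) and the shorter list (18192). The odds ratio of loss of the 5'-most against the 3'-most peak reversed with p-value classes for METTL3 (0.850), METTL14 (0.594), WTAP (0.491) and between the controls (0.584 and 0.637), and its interval held 1 for SETD2 #1 (1.01). With both measures it reversed for METTL14 (0.849), WTAP (0.790) and control peaks absent from the second control (0.628), and its interval held 1 for METTL3 (1.03) and the reverse comparison of the controls (0.966). With 50% overlap the interval for control peaks absent from the second control held 1 (1.04).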

Other observations

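All tests below were chosen after the results were seen, except the coincidence of losses among METTL3, METTL14, WTAP and SETD2 #1, between each of these and the second control, and between the SETD2 shRNAs, within 5 classes of fold enrichment or p-value. Losses differed between chromosomes. Chromosome 13 lost 44.8% (40.1 to 49.6%) of its 435 control peaks in the METTL14 list and 43.0% (38.3 to 47.8%) in the WTAP list, where p-value classes predicted 34.2% and 33.0%, and 33.1% in METTL3 against 26.7%. Chromosome 22 lost 23.4% in METTL14 against 30.1% predicted. For SETD2 #1, chromosome 13 lost 32.0% against 31.5%. Across 23 chromosomes the METTL14 ratio of observed to predicted losses ran with that of second control peaks absent from the control (Pearson r = 0.943, Spearman rho = 0.92), which involves no knockdown, and against that of control peaks absent from the second control (r = -0.699, rho = -0.711). With the other knockdowns the METTL14 ratio had r = 0.963 (WTAP), 0.826 (METTL3), 0.107 (SETD2 #1) and -0.542 (SETD2 #2 against its own control). Chromosomes are not independent replicates.

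Peaks of both controls absent from all 5 knockdown lists numbered 557, where 539 would be lost if SETD2 #2 losses were unrelated to the other 4 lists within p-value classes. Of these, 5 had a p-value at or better than the control median, among them the peaks on chromosome 11 from 110300847 to 110301026 and on chromosome 3 from 126668211 to 126668568. SETD2 #1 lacked 7.53% of control peaks present in the METTL3, METTL14 and WTAP lists and 77.4% (76.3 to 78.6%) of those absent from all 3, and the second control 15.5% and 60.1% (58.8 to 61.4%). These shares were not taken within p-value classes. Of the 5262 control peaks absent from all 3 lists, only 245 had a p-value at or better than the control median. Between 9.42% and 11.2% of peaks in each list overlapped a peak on the opposite strand.

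The coincidence of losses among knockdowns sharing a control has several possible explanations. Random loss of weakly supported peaks is argued against by the METTL14 and WTAP odds ratio of 15.0 within p-value classes. For the shared control alone, the odds ratio with the second control was lower, 1.26 for METTL14 and 2.32 for SETD2 #1. The second control belongs to another set, and across chromosomes METTL14 losses ran against the control peaks absent from it (r = -0.699). These values therefore cannot show how much the shared control contributes. Resemblance of lists of the same set, as the whole cause, would give SETD2 #1, a list of that set, similar values. With METTL3, METTL14 and WTAP its values were 4.79, 3.70 and 3.34, against 7.40 to 15.0 among these 3. The ratio of the nearest values was 1.54 (interval 1.40 to 1.71), but 1.04 and no longer clear of 1 among peaks at or above the median fold enrichment. That ratio bears on resemblance within the set only if the lower enrichment of the SETD2 #1 list does not produce it. A common target of the complex may account for the excess among METTL3, METTL14 and WTAP. The lower median fold enrichment of the SETD2 #1 list, 5.32 against 6.71 to 7.02, or any handling shared by the 3 lists would give the same. Across chromosomes METTL14 losses ran with those of WTAP (r = 0.963) and METTL3 (0.826), but hardly with SETD2 #1 (0.107). They also ran with second control peaks absent from the control (0.943), which involves no knockdown. No second list of low enrichment in that set was analysed here, and these accounts cannot be told apart.

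The coincidence of the 2 SETD2 shRNAs rests on separate controls. Within 10 classes of p-value the odds ratio was 1.56 (1.40 to 1.71), with exonic width added 1.61, and with both measures 1.69, which argues against random loss of weak peaks as the whole cause. Among peaks whose gene had another, non-overlapping peak in both SETD2 lists it was 1.61 (1.42 to 1.83) within p-value classes, which argues against genes leaving the lists altogether as the whole cause. Reduced SETD2 is a candidate explanation, as the coincidence exceeded that of METTL3 with SETD2 #2 by a ratio of 1.52 and that of METTL14 and WTAP by more within p-value classes; with both measures the values with SETD2 #2 were 1.19 (1.05 to 1.35) for METTL3, 1.08 (0.969 to 1.19) for METTL14 and 0.958 (0.854 to 1.06) for WTAP. In the same order their values were 1.02, 0.844 and 0.679 within 10 classes, 1.06, 0.866 and 0.688 with width, and 0.998, 0.866 and 0.653 where the gene had another peak in their own list and in SETD2 #2. An excess was not particular to a SETD2 list: over the control peaks, SETD2 #1 coincided with the second control at 2.32, against 1.43, 1.26 and 1.17 for METTL3, METTL14 and WTAP. With SETD2 #2 over the same peaks it coincided at 2.30, against 1.20, 0.979 and 0.838. These comparisons are not independent, as 7912 of the 11576 control peaks absent from SETD2 #2 were absent from the second control too. Reduced SETD2 therefore cannot be told apart from lower enrichment in both SETD2 lists than in their controls (median fold 5.32 against 6.79, and 3.81 against 4.33).

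The preferential loss of 5'-most peaks differed between the SETD2 shRNAs. For SETD2 #2 weaker support of 5'-most peaks is argued against by the odds ratio of 2.19 within p-value classes. For SETD2 #1 it was 1.01 within p-value classes, and in genes with at least 5 peaks the odds ratios against the last peak were 1.36 (1.12 to 1.67), 1.16 (0.939 to 1.42), 1.34 (1.10 to 1.65) and 1.07 (0.882 to 1.30) from the 5' end, so the excess was not particular to the 5'-most peak, and whether support accounts for it cannot be told apart. In such genes the SETD2 #2 odds ratios were 2.01 (1.64 to 2.52), 1.68, 1.01 (0.801 to 1.28) and 1.18 (0.929 to 1.47) from the 5' end. Position also mattered between the controls, without a knockdown, though in the other direction at the 5' end. There the odds ratios were 0.46 (0.369 to 0.575), 0.929, 1.11 and 1.25 (1.03 to 1.53) for control peaks. For second control peaks they were 0.765 (0.602 to 0.99), 1.2, 1.24 and 1.18. Coverage that declines towards the 5' end may produce a pattern like that of SETD2 #2, and without coverage of the input libraries it cannot be told apart from a biological difference, which was not tested.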
